A study of Mus musculus with 28 samples.

How the data were processed

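Smchd1 and Ctcf binding, H3K4me3 and H3K27me3 were measured by ChIP-seq and DNA methylation by MBD-seq in neural stem cells, per the labels' protocols. Chromatin was crosslinked with formaldehyde and sonicated, and methylated DNA was captured on beads that carry the methyl-CpG binding part of MBD2. Base calling used CASAVA 1.4, peaks were called with MACS2 (version 2) and the genome build was mm10, per the submitters' processing notes. The aligner is not given in the sources used here. The samples fall into 14 groups, of which 11 hold replicate libraries, the group with Ctcf shRNAs holds 1 library for each of 2 hairpins and the whole cell extracts hold 1 library each.

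The deposited files used here are 11 lists of peak summits, each 1 bp wide, with a score that the authors' MACS2 run gave as −log10 of a p-value or q-value. Which of the 2 it is was not given in the sources used here. The lowest scores lay just above 3.301 or 2.301, the −log10 of the thresholds 5e-4 and 5e-3. Per the labels, each list was made from all libraries of its group: Smchd1 in wild-type cells against Smchd1 ChIP in null cells, Ctcf against Ctcf ChIP in wild-type cells with Ctcf shRNAs, and the histone marks and MBD against the whole cell extract of the same genotype. A false summit in a control, or a difference in depth, therefore changes which summits pass the threshold, and list length alone shows no biological change. No columns of per-sample values were used. Coverage tracks and reads were not used here, so the depth per library is unknown and precision can be given only as counting error of shares.

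The MBD labels conflict: the samples titled null cite the list named for wild type and the reverse. Both lists are named by their own names and given no genotype direction.

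Summits on unplaced contigs were left out of all comparisons (their numbers stand in the closing section). Genes were taken from a reference table of 49943 genes, 21887 of them protein-coding, on GRCm38, which is the same assembly as mm10. That table gives gene ends but no strand, exons or sequence. A gene therefore counted as marked when a summit lay within 2 kb of either annotated end, where transcription starts had been planned, exons, introns and untranslated regions are not given, and the planned search for the Ctcf core motif was not run. Random placements used positions between the first and the last annotated gene of each chromosome in place of a map of assembly gaps.

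Nearest distances, overlaps and placements were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Summits of a pair of lists counted as shared when they lay within 1 kb. Smchd1 summits were compared with 10000 random placements that kept the number per chromosome, with two-sided permutation p-values of at least 0.0002. For Ctcf and MBD, placements at H3K4me3 summits are given as well. The p-values were adjusted by Benjamini-Hochberg over 11 targets and, apart, over 28 gene lists. Intervals of shares are exact 95% binomial (Clopper-Pearson) intervals, cover counting error only and treat summits as independent, which neighbouring summits are not. The placements scatter summits one by one too, so their p-values are too small where summits gather.

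Genotype comparisons are descriptions of pooled lists with no test across samples. The permutation tests of the closing section compare summits within these lists. A gene list's null-only minus wild-type-only count was given as a percentile among 10000 random lists of the same size drawn from genes marked in at least 1 list. A cluster's count was given as a percentile among 10000 windows of its length centred on randomly drawn protein-coding genes, called random windows below. Of 30 gene lists fixed before the data were examined, 28 had annotated members. The histone gene lists matched 0 annotated names and were not analysed here.

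Genes were named by a rule fixed before the data were examined: the coding gene nearest to each of the 20 highest Smchd1 summits, fixed-list genes within 20 kb of a Smchd1 summit, for each list of a pair the 10 highest summits with no summit of the other list within 5 kb and a coding gene end within 10 kb, and fixed-list genes marked in 1 list of a pair (the 10 with the highest score where there are more), with the Smchd1 gene always given. Many of the fixed-list genes marked in 1 list, and some others that this rule chose, are not reported here, and some beyond the 10 are. Examples shared by both lists, single positions and the regions of the closing section were chosen after their values were seen.

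The scripts were tested on simulated data. Nearest distances equalled a brute-force search in 300 of 300 cases. For Smchd1 sites near the non-silencing Ctcf list, 26 of 1000 sets of 407 random sites (2.6%) had a placement p under 0.05, and 100 of 100 sets with 10% of sites planted beside Ctcf summits did. For H3K4me3, over 12987 genes, 4 of 1000 random gene lists (0.4%) and 996 of 1000 with 5 planted gains lay above 97.5% of random lists.

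The alternatives were merging of summits within 1 kb, scores of at least 5 or 10, matching within 250 bp or 5 kb, the Smchd1 list at 5e-3, leaving out the sex chromosomes, gene-end distances of 1 kb and 5 kb, cluster flanks of 0 or 100 kb, placement at gene ends and equal numbers of highest-scoring summits in a pair. Each alternative placement used 2000 draws.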

Results

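Smchd1 is a chromatin protein of the structural maintenance of chromosomes family that is needed for stable silencing on the inactive X chromosome and at several gene clusters. Its binding, 2 histone marks, Ctcf binding and DNA methylation were mapped by sequencing in neural stem cells grown from male E14.5 mouse embryo brain, in wild-type cells and in cells homozygous for the MommeD1 null allele of Smchd1. The 28 libraries comprised 2 per genotype for chromatin immunoprecipitation (ChIP) of Smchd1, of H3K4me3 (a mark of active promoters) and of H3K27me3 (the mark laid down by Polycomb repressive complex), 3 per genotype for capture of methylated DNA on the methyl-CpG binding domain of MBD2 (MBD), and 1 whole cell extract per genotype. Ctcf, a zinc finger protein that binds insulators and anchors chromatin loops, was immunoprecipitated from 2 libraries each of untransduced wild-type cells, wild-type cells with a non-silencing short hairpin RNA (shRNA), wild-type cells with Ctcf shRNAs and null cells.

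The authors' processed data were 11 lists of peak summits, single positions in mm10, each called on the pooled libraries of a group, so no value had replicate error and no test between genotypes could be made. On assembled chromosomes the lists held 407 Smchd1 summits at a calling threshold of 5e-4 and 1105 at 5e-3, 23449 wild-type and 24201 null H3K4me3 summits, 732 wild-type and 77 null H3K27me3 summits, 8292 Ctcf summits in untransduced wild-type, 20483 in non-silencing wild-type and 11920 in null cells, and 156188 and 126631 MBD summits in the lists named for wild type and for null. The lists give no read numbers, so the depth behind each list is unknown. Scores are the authors' and serve only to rank summits within a list. At Smchd1 itself (chromosome 17, 71344489 to 71475366), the wild-type and null H3K4me3 lists held 2 and 1 summits, with top scores of 38.3 and 47.5, the MBD lists named for wild type and null held 10 and 9, and the Smchd1, Ctcf and H3K27me3 lists held 0.

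The places bound by Smchd1 in wild-type cells were asked for first. The coding genes nearest to the 20 highest summits of the 5e-4 list included genes of neuronal signalling and of development. The highest, with a score of 28.97, lay inside Mid1, which encodes a microtubule-associated ubiquitin ligase, at X:169987103. Others lay near the potassium channel gene Kcnk9 (score 24.0, 20114 bp from the gene), in the glycine receptor gene Glra1 (20.8), in the imprinted Snrpn transcription unit (18.4 at 7:60243974), beside Snai2, a transcription factor of the neural crest (17.7 and 15.3), in Cacng2, which encodes an AMPA receptor regulatory subunit (17.3), between Hoxa7 and Hoxa9 (17.3 at 6:52221815) and in Hoxd3 (16.9 at 2:74715939). The remaining named genes were Ppp6c, A26c2, Gm52481, Ifna13, Parp8, Mtus2, Caln1, Gpat3, Nrxn3, Iqsec3 and Pcsk2, of which Ppp6c was only the nearest coding gene, 580544 bp away. Chromosomes 5 and 7 held 40 summits each and chromosome 13 held 39, against 5 on X and 1 on Y. Within 2 kb of an annotated end of a protein-coding gene lay 145 summits (35.6%, exact 95% interval 31.0 to 40.5%), against a mean of 5.96% for 10000 random placements on the same chromosomes (two-sided permutation p = 0.0002, the smallest the placements can give, adjusted p = 0.000275 by Benjamini-Hochberg over 11 comparisons). Inside protein-coding genes lay 178 summits (43.7%).

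Smchd1 summits were concentrated in Hox clusters, which set positional identity along the body axis, and in the imprinted Snrpn cluster. HoxD (chromosome 2, 74648225 to 74785142 with 20 kb added on each side) held 11 summits, HoxA (chromosome 6, 52135367 to 52280880) held 10, HoxB (chromosome 11, 96174316 to 96388254) held 6 and HoxC (chromosome 15, 102901131 to 103056856) held 2. The Snrpn cluster (chromosome 7, 58636142 to 62484510) held 12, against 1.06 in the mean of random placements. The permutation p over placements was 0.0002 for HoxA, HoxB, HoxD and Snrpn and 0.0004 for HoxC (adjusted p = 0.000933 and 0.0016 over 28 gene lists fixed before the data were examined).

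In the protocadherin alpha cluster, whose members give single neurons their surface identity, the list held 1 summit (permutation p = 0.0606, adjusted p = 0.189), at 18:37089973 just upstream of Pcdhac1, with a score of 5.85. The 5e-3 list held 3 there (permutation p = 0.001), and a flank of 100 kb added a higher summit of the 5e-4 list (18:37218384, score 9.93), which made 2 (permutation p = 0.002). The Pcdhb, Pcdhg and Igf2r clusters held 0. These 9 clusters together held 42 summits (10.3%) against a random mean of 1.35 and a maximum of 7 (permutation p = 0.0002).

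Of the gene lists that do not form a cluster, developmental transcription factors had 22 summits within 20 kb (adjusted permutation p = 0.000933), of which the 4 at Evx2, beside Hoxd13, were counted in HoxD too. Among the 22 were those at Tbx3 (top score 12.1), Six2 (11.3), Nkx6-1 (10.9), Evx1 (9.69), Evx2 (9.25), Cdx2 (7.90), Gata4, Isl1, Gata3, Nkx2-1, Pax3, Msx1, Wt1 and Pax9. The neuron list had 6 summits (adjusted permutation p = 0.000933), 4 of them at the splicing factor gene Rbfox3 (9.09) and 2 at the glutamate transporter gene Slc17a6 (8.32). Lrif1, which encodes a partner of Smchd1 on the inactive X chromosome, had 3 (top score 11.0 at 3:106721538, adjusted permutation p = 0.0028 for its list of 12 genes). Both p-values rest on neighbouring summits at Rbfox3, Slc17a6 and Lrif1, which the placements scatter one by one. They therefore say little about the other genes of these lists. Imprinted genes outside the Snrpn and Igf2r clusters had 3 summits, at Kcnk9 (11.6) and Grb10 (6.61), with an adjusted permutation p of 0.237. Keratin gene Krt8 had 1. Olfactory receptor genes (7 summits, permutation p = 0.351), Zfp genes (6, p = 0.71) and tRNA genes (2, p = 0.641) did not stand apart from random placement. None lay within 20 kb of the listed genes of the X-inactivation centre, the Rhox cluster, DNA methylation, Polycomb, neural stem cells, glia, germ cells, blood, endothelium, mesenchyme or housekeeping.

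**Figure D1:**
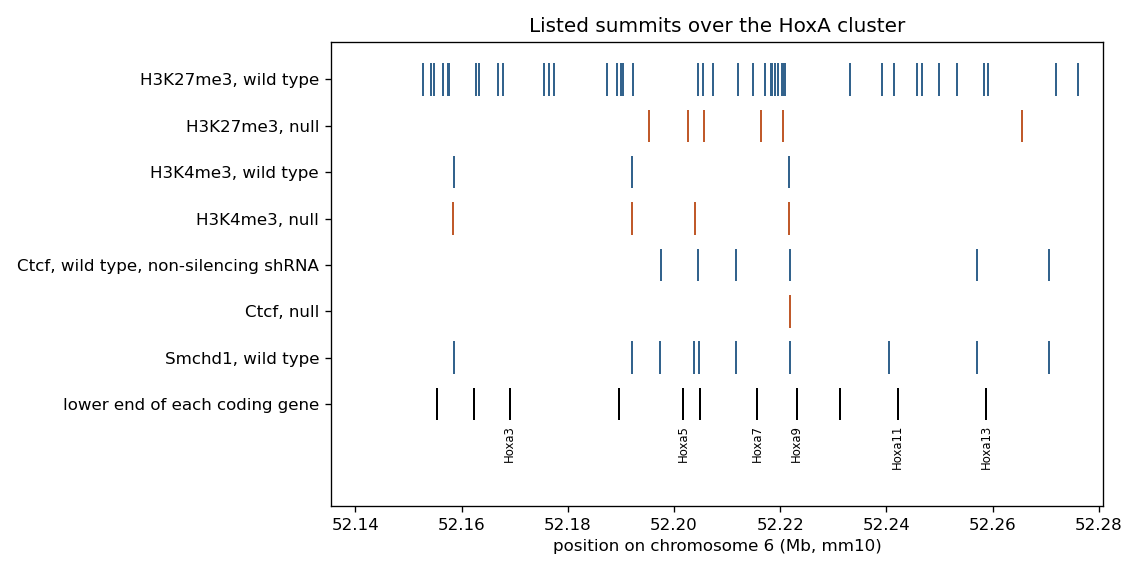
Map of summits over the HoxA cluster on chromosome 6 (position in Mb, mm10), with 1 track per list and the lower coordinate of each coding gene as black ticks. The wild-type H3K27me3 list has 42 summits here and the null list 6, and 10 Smchd1 summits lie among them.

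Smchd1 and Ctcf summits often coincided. At Snai2 (the higher summit), Mtus2, Caln1, Gpat3, Nrxn3 and Hoxa9, Smchd1 summits lay within 50 bp of a Ctcf summit in each of the 3 Ctcf lists. Of 407 Smchd1 summits, 179 (44.0%, exact 95% interval 39.1 to 49.0%) had a wild-type Ctcf summit within 1 kb in either list, against 1.72% for random placement, a 25.5-fold excess (two-sided permutation p = 0.0002, the smallest possible, adjusted p = 0.000275). Placement at H3K4me3 summits gave 15.1% (permutation p = 0.0002). Of the 179, 81.6% had a Ctcf summit within 50 bp, with a median distance of 16 bp. The share was 22.1% for the untransduced list, 43.0% for the non-silencing list and 34.6% for the null list. In HoxA, 7 of the 10 Smchd1 summits had Ctcf of either wild-type list within 1 kb. In HoxD it was 6 of 11, in Snrpn 5 of 12, and in developmental transcription factor genes 14 of 22. The neuron genes Rbfox3 and Slc17a6 had 0 of 6 and Lrif1 0 of 3.

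Promoter marks were the other common neighbour. The Smchd1 summits at Cacng2, Mtus2, Snrpn, Hoxa9, Pcsk2 and the interferon gene Ifna13 lay within 1 kb of H3K4me3 in both genotypes' lists. In all, 146 Smchd1 summits (35.9%, interval 31.2 to 40.7%) had a wild-type H3K4me3 summit within 1 kb, against 1.52% for random placement, at a median distance of 176.5 bp. Placement at gene ends, where many Smchd1 summits lie, gave 29.2% (permutation p = 0.009). Wild-type H3K27me3 lay within 1 kb of 21 (5.16%, interval 3.22 to 7.78%), among them the Hoxa9 summit, against 0.0473% for random placement (permutation p = 0.0002 for both marks). With both wild-type Ctcf and H3K4me3 were 57 summits, 122 had Ctcf alone, 89 had H3K4me3 alone and 139 (34.2%) had neither.

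MBD summits were not enriched at Smchd1 sites over random placement, but the direction depended on the background. Placement at H3K4me3 summits gave 5.48% for the list named for wild type, below the share seen (permutation p = 0.0236). For the list named for null it gave 4.27% (permutation p = 0.225). The list named for wild type lay near 8.35% of them, against 10.9% for random placement (permutation p = 0.102), and the list named for null near 5.65%, against 8.98% (p = 0.0168, adjusted p = 0.0205). The second p rose above 0.05 after merging of neighbouring summits, at the other distances and at the higher scores tried.

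**Figure D2:**
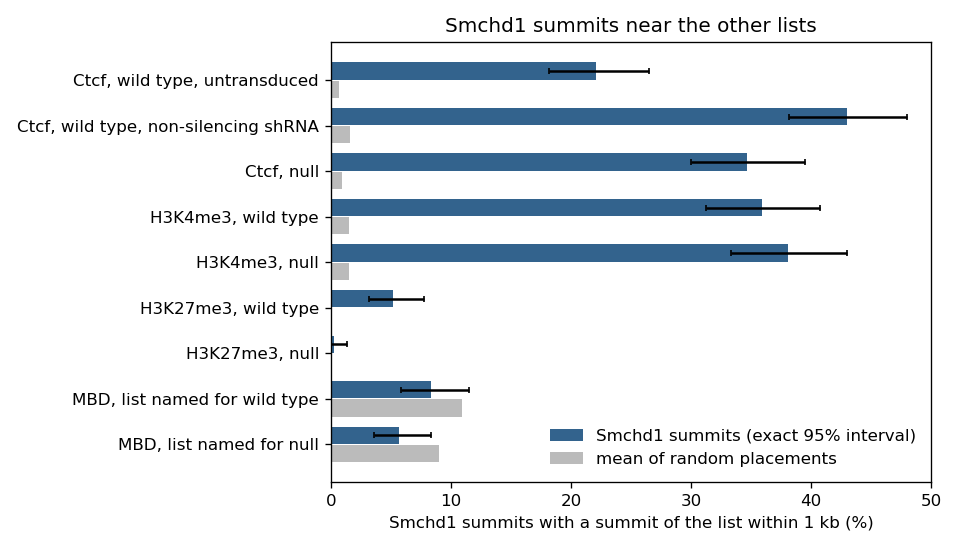
Percentage of the 407 Smchd1 summits with a summit of each other list within 1 kb (blue bars, whiskers are exact 95% binomial intervals), beside the mean of 10000 random placements (grey bars). Ctcf and H3K4me3 shares lie between 22.1% and 43.0%, far above placement, and the MBD shares lie below it.

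H3K4me3 lists of wild-type and null cells were compared for active promoters. The protocadherin alpha genes differed most among the fixed gene lists: 3 of 14 had a wild-type summit within 2 kb of a gene end and 13 had a null one. Pcdha1 to Pcdha10 were listed in null cells only, with null scores of 42.0 at Pcdha8, 36.1 at Pcdha1, 27.8 at Pcdha4 and 22.6 at Pcdha10. Of the protocadherin beta genes, Pcdhb2 (20.7), Pcdhb4, Pcdhb8, Pcdhb15, Pcdhb16, Pcdhb19 and Pcdhb22 were listed in null cells only and Pcdhb21 in wild type only, so that 4 genes had a wild-type summit and 10 a null one. At a score of at least 10 only 3 Pcdhb genes were null only. All 21 Pcdhg genes were listed in both, most through the summit at the downstream end that they share. The net number of null-only genes lay above 100% of 10000 random lists of marked genes for both Pcdha and Pcdhb.

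The null summits at the Pcdha genes lay beside the lower annotated end of each gene, for example at 18:36992426 for Pcdha8 (gene 36992467 to 37187657), 18:36930247 for Pcdha1 and 18:36952754 for Pcdha4. The cluster (chromosome 18, 36910285 to 37208897) held 4 wild-type and 14 null summits, 10 of the latter without a wild-type summit within 1 kb. Random windows of the same length held a mean of 0.374 such summits, and 99.99% held fewer.

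Hoxa5 and Hoxa6 shared a summit listed in null cells only (6:52204034, score 11.7, above 99.72% of random lists for HoxA, in which it counts as 2 genes). Counted as 1 summit without a wild-type counterpart, it put HoxA above 84.46% of random windows. Single genes of other lists also differed. Magel2 of the Snrpn cluster, the neural stem cell gene Pax6 and the developmental regulators Tbx1, Tbx18, Isl1 and Sim1 were listed in wild type only, and H19, Tbr1 of cortical neurons, Gata6, Tbx3 and the epithelial gene Epcam in null only, with scores of 3.61 to 9.08. Of the 22 neural stem cell genes 21 were listed in wild type and 20 in null, among them Sox2, Nes and Olig2 in both, and of the 16 housekeeping genes 15 were listed in both.

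The highest wild-type-only summits, here those with no summit of the other list within 5 kb and a coding gene end within 10 kb, lay at Abcb9 (18.8), Rax (16.1), Pabpc5 (16.1), Albfm1, Pip5k1b, Mrpl9, Gipc2, Capg, Actn2 and Ccdc65. The highest null-only ones lay at Pcdha8, Pcdha1, Pcdha4, Gm51464 (25.4), Srrm4 (22.8), Pcdha10, Pcdhb2, Pcdha2, the kinesin gene Kif2c (19.8) and Gm38699 (18.8). A counterpart within 1 kb existed for 92.6% of wild-type summits (interval 92.3 to 92.9%) and 92.2% of null ones, which left 1733 and 1897 without, while within 250 bp 5551 and 6297 were without. Of 21887 protein-coding genes, 12758 were marked in wild type and 12688 in null, 299 in wild type only and 229 in null only.

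**Figure D3:**
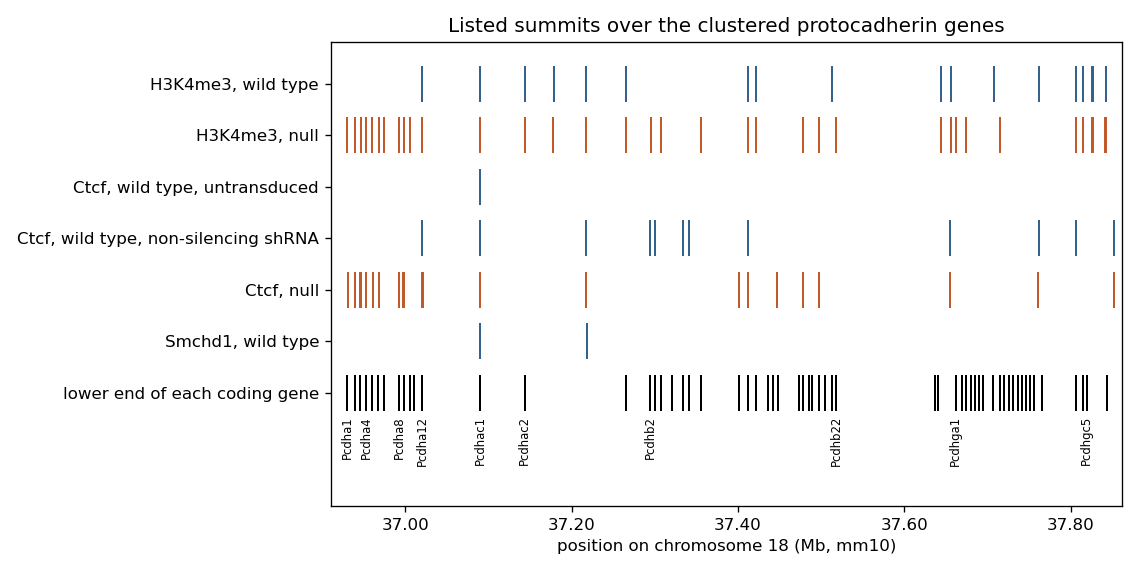
Map of summits over the clustered protocadherin genes on chromosome 18 (position in Mb, mm10), with 1 track per list (wild type blue, null orange) and the lower coordinate of each coding gene as black ticks. Null H3K4me3 summits line up along Pcdha1 to Pcdha10 and null Ctcf summits along 8 of these genes, where the wild-type H3K4me3 and Ctcf lists have 0. The Pcdhg cluster at right, with 20 kb added on each side, holds 12 wild-type and 14 null H3K4me3 summits. These include summits beside the neighbouring gene Taf7.

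H3K27me3 lists were compared for Polycomb marking. The null list was shorter as a whole, and Hox clusters and developmental regulators had fewer summits in it. HoxA held 42 wild-type and 6 null summits, HoxD 28 and 4, HoxC 15 and 5, and HoxB 2 and 2. Of the 60 developmental transcription factors, 41 had a wild-type summit within 2 kb and 8 a null one, 35 being listed in wild type only, among them Otx2, Dlx5 (5.60), En1 (5.60), Nkx2-1 and Pax3. Gata2, Gata6, Lhx1, Gsc and Msx1 were among those listed in both and Pax2 and Tbx3 in null only. The 35 factors fell to 15 at a score of at least 5 and to 8 with equal numbers of highest-scoring summits, which took the 7 wild-type-only HoxA genes to 1, while gene ends within 5 kb took them to 4.

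The neuronal regulators Neurod1, Neurod2, Neurog2 and Tbr1 were listed in wild type only, as were the mesenchymal regulators Twist1 and Foxc2. By the rule of 5 kb between lists and 10 kb to a gene end, the highest wild-type-only summits lay at Foxd3 (4:99659004, score 7.95), Gfi1 (7.95), Nkx2-3 (7.73), Evx2, Fcgr3, Nr5a1, Ebf2, Dlx2, Tal1 and Nkx3-2. The null-only ones lay at Hoxb9 (5.96), Hoxb13, Pitx1, Nkx2-6, Obi1, Hoxc13, Twist1 (5005 bp from the gene), Tbx3 and Hoxa13 (4638 bp), although within 2 kb of a gene end Twist1 and Hoxa13 were listed in wild type only and Hoxc13 in both. No summit of either genotype lay on X or Y, and none at the clustered protocadherins or the Snrpn cluster.

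Genes marked numbered 186 in wild type and 31 in null, of which 24 were marked in both. Of the 732 wild-type summits, 7.24% (interval 5.47 to 9.36%) had a null summit within 1 kb, a share that the shorter null list keeps low by itself. Of the 77 null summits, 46.8% (35.3 to 58.5%) had a wild-type one. With equal numbers of highest-scoring summits, 70 wild-type and 69 null summits had no counterpart. Net counts of null-only minus wild-type-only genes lay above 65.12% of random lists of marked genes for developmental factors, 67.29% for HoxA, 85.81% for HoxB, 91.61% for HoxD and 93.67% for HoxC, all toward fewer wild-type-only genes than in most random lists. The neuron list went the other way, with a net count of -4 against a random mean of -3.20. Of random lists, 51.22% lay above it, so its 4 wild-type-only genes do not stand apart.

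**Figure D4:**
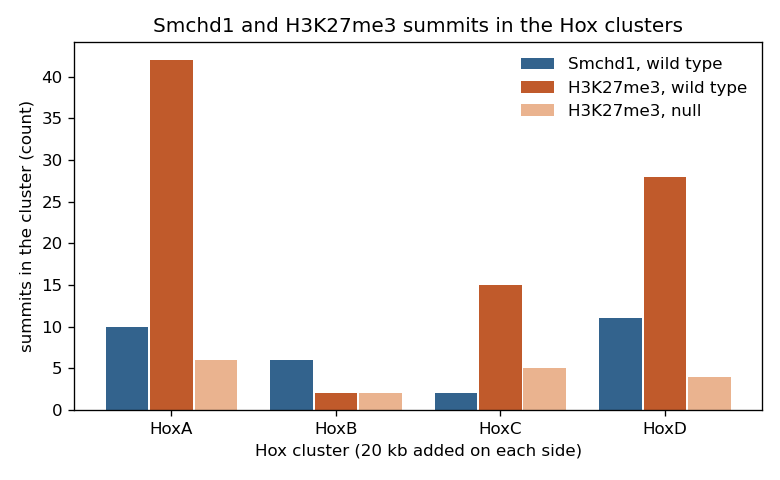
Number of Smchd1 and H3K27me3 summits in each Hox cluster with 20 kb added on each side (bars start at 0, counts of pooled lists without error). H3K27me3 counts are 42 and 6 at HoxA and 28 and 4 at HoxD in wild type and null, and 2 and 2 at HoxB.

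Ctcf lists were compared with the difference between both wild-type lists as the only measure of spread. The protocadherin alpha cluster again stood apart: the untransduced list had 1 summit, the non-silencing list 2 and the null list 14, of which 11 lay in neither wild-type list. Pcdha1 to Pcdha6, Pcdha8 and Pcdha9 had a null summit and no wild-type one, with the highest null scores at Pcdha4 (13.2) and Pcdha8 (13.1), and Pcdhac1 had one in all 3 lists. The net number of null-only Pcdha genes was 8 against the non-silencing list, above 100% of random lists, and 9 against the untransduced list, above 99.94%. For Pcdhb, 7 genes were null only against the untransduced list (above 99.91%), although these rest on 5 summits, above 95.44% of random windows, and 6 null only with 4 wild type only against the non-silencing list (above 98.12%). At score 10 or more only 2 Pcdha genes were null only against either wild-type list.

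In HoxA the direction was opposite: the lists held 3 untransduced, 6 non-silencing and 1 null summits. In the same order HoxB held 2, 3 and 5, HoxD 2, 5 and 5 and HoxC 1, 2 and 1. Null summits in neither wild-type list numbered 4 in HoxB, above 99.8% of random windows, and 2 in HoxD, above 96.8%. Hoxd11 was null only in both comparisons, and Hoxd12 and Hoxd13 only against the untransduced list. Hoxa3 and Hoxa13 had a summit in both wild-type lists and none in null, and Hoxa5 and Hoxa6 in the non-silencing list only, while Hoxa9 had one in all 3. The 4 HoxA genes listed in the longer non-silencing list and not in null fell to 1 with equal numbers of highest-scoring summits, to 1 at a score of at least 10 and to 2 with gene ends within 1 kb. Hoxb5 and Hoxb6 shared a null summit absent from both wild-type lists (11:96303228, score 15.9). Single genes of other lists differed too. Of the DNA methylation genes, Mbd1 was listed in both wild-type lists, Dnmt3l and Zbtb33 in the non-silencing list, and none in null. Tubb3 was null only in both comparisons, Foxa2 and Gapdh only against the untransduced list, and Pgk1, Nkx2-2, Cdh5, Vim and Acta2 were wild type only.

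The highest null summits without an untransduced counterpart lay at Pigt (24.9), Ube2g2 (24.4), Sh2b3, Polr2j, Mark3, Rab27a, Ubtf, A530032D15Rik, Trappc5 and Ankrd39, all within 50 bp of a non-silencing wild-type summit. Those without a non-silencing counterpart lay at Thap12 (21.8), Setbp1 (18.7), Ptger1, Zbtb34, Ccdc126, Amz1, Cracdl, C130026I21Rik, Atp10b and Hoxb5. Among these, only Ptger1, Amz1, C130026I21Rik and Hoxb5 also lacked an untransduced summit within 1 kb. The highest non-silencing summits without a null counterpart lay at 1700012B09Rik (29.4), Pirt (29.3), Gnaz, Fmnl3, Nicn1, Me1, Igfbp2, Gpr19, Otos and Tchp. The highest untransduced ones lay at Pgk1 (190.9), Mlkl, Ube2m and Ripk1. For some summits inside Ripk1, the nearest gene end was that of Serpinb6a. Of the non-silencing ones, all but those at 1700012B09Rik, Igfbp2 and Otos had an untransduced summit within 1 kb. Of the untransduced ones, only that at Pgk1 had a non-silencing summit within 1 kb.

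The wild-type lists also differed from each other. A counterpart within 1 kb existed for 85.6% of untransduced summits in the non-silencing list and 35.5% the other way. Of untransduced summits 61.7% had a null counterpart and of null ones 43.3% an untransduced one. Of non-silencing summits 44.7% had a null counterpart and of null ones 75.7% a non-silencing one. With equal numbers of highest-scoring summits, 5390 non-silencing and 5358 null summits of 11920 each had no counterpart, and 4023 untransduced and 4031 null summits of 8292 each. In neither wild-type list lay 2530 null summits (21.2%).

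MBD lists were compared for DNA methylation, with a conflict in the labels: samples titled null cite the list named for wild type and the reverse, so no genotype direction is given. HoxA genes, among them Hoxa9, had summits within 2 kb only in the list named for null, and the net count for HoxA lay above 100% of random lists and its number of such summits above 98.49% of random windows. At the other end, the genes Ndn, Mkrn3 and Peg12 of the imprinted Snrpn cluster (scores 9.11, 18.5 and 40.2) were listed only in the list named for wild type, a net count above only 0.15% of random lists. In the whole cluster, 15 of 79 summits of that list had no counterpart, and 1 of 61 of the list named for null. More than 15 summits found only in the list named for wild type lay in 92.91% of random windows. Window counts do not allow for how many summits a stretch holds, so this gives no direction. By gene ends within 2 kb, Smchd1, Smc3 and Stag1 too were listed only in the list named for wild type (above 0.08%), although both lists held summits inside Smchd1. Tbx5 was listed only in the list named for null (29.4). Germ cell genes, which carry promoter methylation in somatic cells, were listed nearly throughout, 22 of 24 in the list named for wild type and 21 in the list named for null, among them Dazl, Ddx4 and Sycp3 in both.

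The highest summits found only in the list named for wild type lay at Pcdha4 (18:36954658, score 51.6), Slc48a1, Peg12, N4bp3, Gm46382, Thbs2, Zfp131, Tipin, 4930447A16Rik and Nfib. Among the highest found only in the list named for null were those at Gramd2 (16.5), Nup188 (16.3), Nr2e3, Prkcb, Wdr64, Ndfip2, Aqp1, Meox2 and Neb. Counterparts within 1 kb existed for 82.5% of the summits of the list named for wild type and 98.2% of those of the list named for null, which left 27281 and 2301, or 10513 and 9752 with equal numbers of highest-scoring summits. Genes marked numbered 10305 and 9157, with 1283 and 135 in a single list.

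Smchd1 sites were finally followed into the null lists. Ctcf at these sites was listed in null cells at 141 places (34.6%, exact 95% interval 30.0 to 39.5%), between the untransduced (90, 22.1%, 18.2 to 26.5%) and non-silencing (175, 43.0%, 38.1 to 48.0%) wild-type lists. Sites with null but no untransduced Ctcf numbered 66 and the reverse 15, while sites with non-silencing but no null Ctcf numbered 56 and the reverse 22. In HoxA 7 of 10 Smchd1 sites had Ctcf in either wild-type list and 1 had null Ctcf. In the same order, HoxD had 6 and 5 of 11 and Snrpn 5 and 5 of 12. Both wild-type lists together are set here against a single null list. In HoxA the untransduced list held 3 Ctcf summits, the longer non-silencing list 6 and the null list 1. H3K4me3 was listed at 35.9% of sites in wild type and 38.1% in null (33.3 to 43.0%), with 6 wild-type-only and 15 null-only sites, but within 250 bp the order turned, at 24.3% and 23.8%. H3K27me3 was listed at 21 sites in wild type, among them the Hoxa9 summit, and at 1 in null. The null H3K27me3 list held 77 summits against 732 in wild type, which keeps its count low by itself. MBD was listed at 12 sites only in the list named for wild type and at 1 only in the list named for null. With the non-silencing list shortened to the length of the null list, the order turned, the null share being higher by 7.62 percentage points.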

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

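No comparison used the summits on unplaced contigs, and each list that holds any is given here as a value, with no control list to set it against. The non-silencing Ctcf list had 15, the untransduced list 9 and the null list 13. The wild-type H3K4me3 list had 7 and the null list 10. The MBD lists named for wild type and for null had 206 and 181. The Smchd1 list at 5e-3 had 8 and that at 5e-4 had 3.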

How the results depend on the processing

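No paired analysis was possible because the libraries of each group were pooled into 1 list, which also ruled out leaving out a replicate, and no alternative here was added after the data were seen. Not run were the Ctcf motif alternatives, which need sequence, and a score of at least 10 for the H3K27me3 pair, which empties the null list. The cause of each change below was not tested, except that stricter scores, other distances and equal numbers change by construction how many summits can match. Of the alternative values of the main results, 163 kept their side of the threshold or stayed within their interval or 1.5 times the count, 43 moved further, 6 lost the threshold and 2 gained it. Of the values for single clusters, gene lists and differences, 113 stayed, 10 moved, 2 gained the threshold, 1 lost it and 2 reversed. Pcdha kept 10 to 11 null-only H3K4me3 genes in each setting tried, and the share of Smchd1 summits near Ctcf stayed above random placement in each, as did that near H3K4me3, though only at 35.9% against 29.2% with placement at gene ends.

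With the Smchd1 list at 5e-3, 36.5% of Smchd1 summits had non-silencing and 28.1% null Ctcf. With equal numbers of highest-scoring summits, summits without a counterpart numbered 5390 non-silencing and 5358 null Ctcf, 4031 null Ctcf against untransduced, 70 wild-type and 69 null H3K27me3, and 10513 and 9752 in the MBD lists named for wild type and null. At Smchd1 sites that setting gave 27.03% for non-silencing Ctcf and 29.0% for null Ctcf (against untransduced), and the null minus non-silencing difference reversed from -8.35 to 7.62 percentage points.

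With gene ends within 1 kb, 1082 genes had non-silencing and no null Ctcf. Within 5 kb the number was 2720, with 986 untransduced and no null, 2057 null and no untransduced, and 88 only in the MBD list named for null. At a score of at least 10, summits without a counterpart numbered 7474 non-silencing and 1032 null Ctcf, 1727 untransduced and 2302 null Ctcf, and 964 wild-type and 1102 null H3K4me3. Smchd1 sites then had untransduced Ctcf at 14.1%, null Ctcf at 28.2%, wild-type H3K4me3 at 18.3%, null H3K4me3 at 21.1%, wild-type H3K27me3 at 0% (permutation p = 1.0) and the MBD list named for null at 4.23% (permutation p = 0.442). At a score of at least 5, H3K27me3 summits without a counterpart numbered 199 and 6, and the MBD list named for null lay at 6.51% of sites (permutation p = 0.158).

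With matching within 250 bp, summits without a counterpart numbered 5551 wild-type and 6297 null H3K4me3, and 4522 in the MBD list named for null. Smchd1 sites then had H3K4me3 at 24.3% in wild type and 23.8% in null, so that the null minus wild-type difference reversed from 2.21 to -0.491 percentage points, and MBD at 2.95% and 2.21% in the lists named for wild type and null (permutation p = 0.82 for the second). Within 5 kb the numbers were 1118 and 954 for H3K4me3, 13 for null H3K27me3 and 14599 and 1094 for the MBD lists, and sites had non-silencing Ctcf at 52.1% and MBD at 31.4% and 27.3% (permutation p = 0.096 for the second).

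Merging summits within 1 kb put the MBD list named for null at 6.06% of sites (permutation p = 0.085). The MBD list named for wild type passed the threshold without the sex chromosomes, at 7.73% (permutation p = 0.039, below placement), and with placement at gene ends, at 8.35% (permutation p = 0.001).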

Other observations

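All tests weighed in this part were chosen after the results were seen. In the H3K27me3 pattern the bound on shared places was met at 5 kb, and the demand for it at 1 kb too came after both values were seen. In the Pcdha pattern the tests on list length replaced an earlier one in which equal numbers removed few summits. In the Ctcf pattern the explanation that names Smchd1 sites in particular was reworded after its outcome and the general difference between Ctcf lists added.

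Smchd1 summits gathered in a few windows of 1 Mb. Windows over HoxD (chromosome 2, 74 to 75 Mb) and HoxA (chromosome 6, 52 to 53 Mb) held 11 each, a window in the Snrpn cluster (chromosome 7, 60 to 61 Mb) held 10 and one over HoxB (chromosome 11, 96 to 97 Mb) held 8. A window on chromosome 13 (66 to 67 Mb), in no fixed list, held 11 as well, while the fullest window in 1000 random sets held 5. The stretch from 65 to 67 Mb there held 14 summits that merged into 9 sites, with 24 coding genes, of which 13 have provisional Gm or LOC names. A wild-type Ctcf summit lay within 1 kb of 1 of the 14 and an H3K4me3 summit of either genotype within 1 kb of 0.

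In the untransduced Ctcf list, 14 summits with scores of at least 25 had no counterpart in the other two Ctcf lists and lay at 3 genes, Mlkl and Ripk1, which encode proteins of necroptosis, and Ube2m, which encodes an enzyme of neddylation. The highest, 116.7, lay at Mlkl (8:111333687), and the highest at Ube2m was 51.4 and near Ripk1 46.8. Since the other wild-type list lacks these summits too, they show no difference between genotypes, and their origin was not tested.

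The null H3K27me3 list was shorter than the wild-type list, with HoxA at 6 against 42 summits and Neurod1, Neurod2, Neurog2 and Tbr1 absent from it. A different set of marked places cannot be told apart from a thinner sample of the same places, since 83.1% of null summits (64 of 77, exact 95% interval 72.9 to 90.7%) lay within 5 kb of a wild-type summit but 46.8% (36 of 77, 35.3 to 58.5%) within 1 kb. A less sensitive null list cannot be told apart from a loss of the mark either: wild-type scores of 150 summits with a null neighbour and 582 without gave an area under the curve of 0.524 (permutation p = 0.357), and depth was not used here. Scores in these lists were low and often tied, which leaves little to rank by. A loss of H3K27me3 in Smchd1 null cells stays an untested biological explanation.

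Pcdha genes carried H3K4me3 and Ctcf in the null lists only, together at 8 of the 14 genes. Against longer or more sensitive null lists as the cause stand shares set beside null summits matched on score. Of 14 null H3K4me3 summits in the cluster, 71.4% had no wild-type counterpart, against 4.78% (permutation p = 0.0002). Of 14 null Ctcf summits, 78.6% had no non-silencing counterpart against 25.2% (permutation p = 0.0002). For the untransduced list the shares were 92.9% and 60.4% (permutation p = 0.0156). The cluster was taken up because of these unmatched summits, so the p-values are no separate support. They also take summits as independent, while some null Ctcf summits lay within 1 kb of each other (18:36946032 and 18:36946663). The p-value for the untransduced list may not hold for separate sites. More neurons or glia in the null cultures, in which Pcdha genes are active, cannot be excluded: the 20 marked genes of those lists (35 listed) had 1 null-only and 0 wild-type-only, above 78.8% of random lists. A candidate explanation is that these promoters are active and bound by Ctcf in cells without Smchd1, although the 5e-4 list held only 1 Smchd1 summit in the cluster, at Pcdhac1, and 1 just beyond it (18:37218384), and the 5e-3 list held 3 in the cluster. Whether that follows from the genotype or from the cultures used was not tested. The null Ctcf list was called against wild-type cells with Ctcf shRNAs. Ctcf binding at these promoters was therefore not told apart from a difference in background between the genotypes.

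Ctcf at Smchd1 sites was listed in null cells more often than in untransduced wild-type cells, by 12.5 percentage points, or 6.88 with equal numbers of highest-scoring summits. That may be a property of the lists: the untransduced and non-silencing wild-type lists differed there by 20.9 points at full length. These lists hold 8292 and 20483 summits and were not compared at equal numbers, so the 20.9 points cannot tell list length from other causes. With the non-silencing list shortened to the length of the null list, the null share was the higher one. Null Ctcf summits at Smchd1 sites lacked an untransduced counterpart in 44.2% of 138, against 47.5% of null summits matched on score (permutation p = 0.44), as a general shortfall of the untransduced list would give. A shortfall at Smchd1 sites in particular was not seen, since non-silencing summits there lacked an untransduced counterpart less often than matched ones, 48.6% of 173 against 60.2% (permutation p = 0.001). Wild-type summits there lacked a null counterpart less often than matched ones (untransduced 16.5% against 36.4%, non-silencing 31.8% against 51.4%, permutation p = 0.0002 for both), the reverse of a loss particular to these sites, and null summits lacked a non-silencing one in 15.9% against 17.2% (permutation p = 0.766), which leaves a gain, or an effect of genotype on Ctcf in general, open.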
